A study of Mus musculus with 3 samples.

How the data were processed

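Gene expression was measured by RNA-seq in 3 libraries of sorted mouse bone marrow pre-B cells, all of 1 group. The deposited files hold raw read counts per gene, one value for each Entrez gene identifier, together with a gene length in bases. Reads were summarised with featureCounts on the mm9 build, per the submitters' processing notes, which also name CASAVA. Its version was 1.8.2 for replicates 1 and 2 and 1.8.0 for replicate 3, per the labels. The aligner, the gene annotation, the read length, the strand setting and the tool versions other than that of CASAVA are not given in the sources used here. RNA was prepared from lysed cell pellets with a column kit and libraries with the standard Illumina procedure, per the labels' protocols. The count columns of the series table equal those of the sample files. Replicate numbers come from the sample titles.

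Symbols and gene types were taken from an annotation of GRCm38 by Entrez identifier, for names only. No coordinates are printed, since its build is not that of the files. Of 26286 identifiers, 24176 matched a symbol and 2110 did not; the unmatched took 2.90 ± 0.06% of the counts (SD, n = 3). Of the 370 list genes, 368 matched, some through an older symbol. Without a stated rule for reads that align to several genes or to either strand, counts of pseudogenes, paralogs, and overlapping or antisense genes are uncertain.

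Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Library sizes were scaled by TMM, with factors of 1.0003, 0.9969 and 1.0028 for replicates 1, 2 and 3. RPKM was computed here from the deposited counts and gene lengths, and log2(RPKM + 0.5) is the scale of list levels. For tests, filterByExpr (minimum count 10, minimum total 15) kept 12147 genes. Totals ranged from 12021576 to 32086649 counts, so a gene of replicate 3 has more counts, and less counting error, at the same level. Intervals and the floor of 3 counts cover counting error only.

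List levels were set against 10000 random lists of the same size from the 17423 genes with a count. List shifts were set against 10000 random lists matched on mean expression in 20 bins, as log2 CPM with a prior count of 2. Differences of 2 lists or genes were taken within each library, with an exact sign-flip test whose smallest two-sided p is 0.25 for 3 libraries, so that none of these could pass 0.05. Of the 11 such differences, 10 had 1 sign in all 3 libraries. Spread was tested by chi-square against Poisson counts and by an F test of each gene's quasi-dispersion against the prior (prior degrees of freedom 5.92) in an intercept-only fit. The CASAVA comparison used glmQLFit and glmQLFTest, with DESeq2 1.42.0 as an alternative. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05.

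The 30 lists, the main tests and the rule for naming genes were fixed before the data were examined. Tests and lists chosen later are named as such in the closing section. Named are the sort gate genes, the 4 highest and 2 lowest members of each list (all members of lists of at most 7), the 10 genes with the highest level, up to 10 genes past the variability test, up to 5 per direction in the CASAVA comparison, the genes of planned differences and the sex-linked genes. Not every gene that the rule allows is named. Genes chosen after their values were seen are said to be so.

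The tests were tried on simulated data with known answers. Of 100 genes made 4-fold higher or lower in 1 library against 2, 92 were recovered, and of 100 made 2-fold higher or lower, 50. There were 9 false calls among the 12240 genes of that simulation. Of 200 genes given added spread, the variability test recovered 132 with 0 false calls over 12268 genes. In the simulations of both tests, all genes shared 1 dispersion before any change was added. In the data the dispersion differs between genes (prior degrees of freedom 5.92), so fewer such genes may be recovered there. The Poisson test called 0 of 12327 genes in counts without added spread. A list shifted by 0.5 in 1 library was recovered, with 2 false calls among random lists. A list drawn from the highest 10% of 17423 genes was called high and one from the highest 25% was not. This was 1 draw of each kind, so it does not set how far from the middle a list has to lie to pass.

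Alternatives were DESeq2 size factors or no scaling, all genes with a count in place of the filter, TPM or CPM in place of RPKM, other pseudocounts and minimum levels, a robust fit, another prior count and leaving out each replicate. Thinning replicate 3 to the smallest total, and leaving out replicates for the list shifts, were added after seeing the data. For 1 of the closing tests, words of 31 bases shared between genes were counted in the GRCm38 transcripts. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.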

Results

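The RNA of sorted mouse pre-B cells was sequenced in 3 libraries that form a single group. The donors carried a doxycycline-responsive transactivator together with an inducible cassette that links GFP to a control short hairpin RNA. Doxycycline was given for 3 days, and marrow cells positive for GFP, B220 and CD25 and negative for surface IgM and Kit were collected by flow cytometry. The labels set no second condition against this group, so the levels of genes and gene lists, and the spread between the libraries, are the measurements. Total counts were 12418054 in replicate 1, 12021576 in replicate 2 and 32086649 in replicate 3, a 2.67-fold range. The labels do not say whether each library came from a separate animal, so the spread between these samples may be technical in part. For replicate 1, the sex-linked counts below argue against the same donors as the others. P-values of gene lists come from random lists of genes, and those of the Poisson test from counting noise. Neither kind measures spread between animals. Levels are given as RPKM, read counts scaled to gene length and library size, as mean ± SD over the 3 libraries. Genes are identified by the Entrez numbers of the files.

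The genes behind the sort gate came first. Ighm (Entrez 16019), the constant region of the mu heavy chain, had the highest level of any gene, at 6749 ± 498 RPKM (n = 3). Ptprc (Entrez 19264), which encodes the B220 form of CD45, stood at 107 ± 9.09 RPKM. Il2ra (Entrez 16184), the CD25 chain used as the positive gate, stood at 89.3 ± 17.7 RPKM, against 0.791 ± 0.327 RPKM for Kit (Entrez 16590), the negative gate. On the log2(RPKM + 0.5) scale Il2ra exceeded Kit by 6.14 ± 0.30, or 70.3-fold, and the difference lay between 5.79 and 6.31 in every library. Surface IgM was the gate, not its transcript, so the Ighm level does not check that part of the sort.

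At least 1 RPKM in every library was reached by 11146 genes, 42.4% of the 26286 in the table. After Ighm, the 10 highest levels included Igkc (Entrez 16071), the kappa light chain constant region, at 2941 ± 415 RPKM and B2m (Entrez 12010), the light chain of class I histocompatibility molecules, at 1382 ± 86.6 RPKM. The heavy chain joining segment Ighj4 stood at 1629 ± 61.4 RPKM and the microRNA gene Mir682 at 1777 ± 107 RPKM, over lengths of only 54 and 96 bases, so that few reads give a high value. The annotated pseudogenes Gm10925, at 5514 ± 418 RPKM, and Gm6421, at 1334 ± 45.1 RPKM, and 3 Entrez identifiers with no symbol in the annotation (497210, 100503203 and 100503054, between 1441 and 1872 RPKM) made up the rest. Reads of pseudogenes can come from near-identical copies, so these values are uncertain. The 10 highest genes by count took 4.91%, 4.997% and 4.57% of the counts of replicates 1, 2 and 3.

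The levels of 30 gene lists, chosen before the data were examined, asked which programs the sorted cells expressed. B-lineage transcription factors were high throughout: all 20 exceeded 1 RPKM in every library, and the list median was 7.41 ± 0.08 on the log2(RPKM + 0.5) scale, against 2.56 for all 17423 genes with a count. The leading members were Spib (868 ± 28.4 RPKM), Pou2af1 (721 ± 36.9 RPKM), Tcf3 (423 ± 20.8 RPKM) and Myb (331 ± 28.3 RPKM), and the lowest were Runx1 (21.0 ± 0.99 RPKM) and Bcl11a (14.3 ± 1.34 RPKM). B-cell receptor signalling genes had a median of 6.74, led by the kinase Syk (623 ± 26.1 RPKM), Cd72 (455 ± 25.4 RPKM) and the adaptor Dok3 (397 ± 30.5 RPKM). The scaffold Bank1 was the lowest member, at 6.88 ± 0.74 RPKM.

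The pre-B receptor complex list had the highest median of the 30, at 9.49 ± 0.07, but its members were far apart. The signalling chains Cd79b (1297 ± 62.2 RPKM) and Cd79a (721 ± 33.9 RPKM) and the chaperone-like Vpreb3 (1136 ± 94.7 RPKM) stood beside Ighm. The surrogate light chain genes were much lower, with Igll1 at 34.1 ± 7.46 RPKM, Vpreb1 at 25.0 ± 5.06 RPKM and Vpreb2 at 1.64 ± 0.32 RPKM. Vpreb1 and Vpreb2 are near-identical, so the split of reads between them is uncertain. Igkc exceeded Igll1 by 6.42 ± 0.50 on the log2 scale, 85.9-fold (4.98 with CPM), with the same sign in each library.

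Among the genes of V(D)J recombination and end joining, the recombinase subunit Rag1 stood at 401 ± 56.7 RPKM, the end-joining protein Xrcc6 at 332.5 ± 43.7 RPKM, the polymerase Polm at 140 ± 24.6 RPKM and Hmgb2 at 74.2 ± 8.33 RPKM. Terminal transferase, Dntt, was near the bottom of its list at 4.997 ± 0.51 RPKM, and the polymerase Poll at 3.26 ± 0.43 RPKM. The list median, 3.73, was not separated from random lists (adjusted p = 0.294), although with CPM in place of RPKM it was (adjusted p = 0.000857). Rag1 exceeded Dntt by 6.18 ± 0.34, 72.7-fold (7.90 with CPM).

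Immunoglobulin constant regions covered the widest range of any B-cell list. Below Ighm and Igkc came the lambda constant regions Iglc3 (519 ± 53.7 RPKM) and Iglc1 (435 ± 58.2 RPKM), and at the bottom Ighg1 (0.12 ± 0.021 RPKM) and Ighe (0.064 ± 0.057 RPKM), the constant regions of IgG1 and IgE. The list lay above random lists (adjusted p = 0.0440), a call lost with CPM (0.4001), with low values filtered (0.0757) and without replicate 2 (0.0600).

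Genes of proliferation and of cell cycle exit were high in the same libraries. The mitosis list had a median of 6.24 ± 0.25, led by topoisomerase Top2a (336 ± 55.7 RPKM), the proliferation marker Mki67 (259 ± 42.3 RPKM), cyclin Ccna2 (181 ± 40.4 RPKM) and Ube2c (165 ± 32.4 RPKM). Its lowest members, Bub1 (30.0 ± 5.80 RPKM) and Ccnb1 (28.6 ± 5.83 RPKM), still stood far above 1 RPKM. The DNA replication list had a median of 5.95 ± 0.25, with the ribonucleotide reductase subunits Rrm2 (165 ± 20.8 RPKM) and Rrm1 (89.1 ± 14.1 RPKM), Uhrf1 (126 ± 25.6 RPKM) and the sliding clamp Pcna (120 ± 27.1 RPKM) at the top. Cell cycle exit genes reached 6.19 ± 0.06, with the antiproliferative Btg2 (241 ± 13.2 RPKM) and Btg1 (204 ± 0.73 RPKM), Ccng2 (136 ± 9.96 RPKM) and the inhibitor Cdkn2d (113 ± 10.496 RPKM). The exit list differed from the mitosis list by -0.05 ± 0.19, less than the spread between libraries (exact sign-flip test, two-sided p = 0.75), and by 0.044 without replicate 3. Its difference from the DNA replication list, 0.24 ± 0.20, had 1 sign in all 3 libraries but became -0.51 with CPM. For single genes, the planned difference of the exit gene Cdkn1b minus Mki67 was -1.31 ± 0.37, or 0.404-fold, and below 0 in all 3 libraries.

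Single members of 2 small families stood apart. Of the D-type cyclins, Ccnd3 was at 293 ± 70.2 RPKM, against 1.57 ± 0.22 RPKM for Ccnd2 and 1.06 ± 0.37 RPKM for Ccnd1, and Ccnd3 exceeded Ccnd2 by 7.13 ± 0.35 on the log2 scale, 139.9-fold (6.10 with CPM). Of the survival genes of the BCL2 family, Mcl1 (164 ± 15.3 RPKM) and Bcl2l1 (122.6 ± 3.88 RPKM) were high, whereas Bcl2l2 stood at 1.95 ± 0.57 RPKM and Bcl2 itself at 0.304 ± 0.106 RPKM. The death genes were led by Bmf (77.6 ± 20.9 RPKM), Bax (42.6 ± 0.99 RPKM), Bak1 (31.6 ± 0.86 RPKM) and Bcl2l11 (13.5 ± 1.78 RPKM), and Hrk had no counts, which allows up to 0.047 RPKM (3 counts in 1 library). The survival list exceeded the death list by 0.77 ± 0.25 (1.502 with CPM).

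Other lists around the pre-B stage held a few high genes among lower ones. In IL-7 receptor signalling, Il7r (215 ± 30.6 RPKM), the kinases Pim1 (138 ± 2.74 RPKM) and Jak1 (70.7 ± 4.50 RPKM) and the common gamma chain Il2rg (41.7 ± 3.26 RPKM) contrasted with Mycn (0.860 ± 0.299 RPKM) and Socs3 (0.632 ± 0.441 RPKM). Homing and adhesion genes were led by the chemokine receptor Cxcr4 (406 ± 68.8 RPKM), then the integrin chain Itga4 (53.3 ± 12.3 RPKM) and S1pr4 (52.95 ± 2.64 RPKM), with Cxcr5 (0.591 ± 0.084 RPKM) and Ccr9 (0.496 ± 0.213 RPKM) lowest. Of the p53 targets, Trp53inp1 (206 ± 22.8 RPKM) stood above Mdm2 (57.8 ± 2.12 RPKM), and Eda2r had no counts, which allows up to 0.043 RPKM. The small RNA pathway ran from Ago1 (35.2 ± 2.90 RPKM) and Tnrc6c (26.1 ± 1.96 RPKM) down to Prkra (4.04 ± 0.10 RPKM) and Ago3 (3.69 ± 0.36 RPKM). Interferon response genes had a median of 1.52, with Stat2 (33.6 ± 1.98 RPKM) among the highest and Rsad2 (0.270 ± 0.081 RPKM) and Ifi44 (0.159 ± 0.030 RPKM) lowest.

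The housekeeping list was led by B2m, Actb (1281 ± 105 RPKM), Rplp0 (435 ± 42.1 RPKM) and Ppia (246 ± 26.03 RPKM). Gapdh, a glycolytic enzyme gene with many processed copies in the genome, had 2.35 ± 0.20 RPKM, from 38, 36 and 84 counts. How reads shared with those copies were counted is not given in the sources used here, so this level is uncertain.

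**Figure D1:**
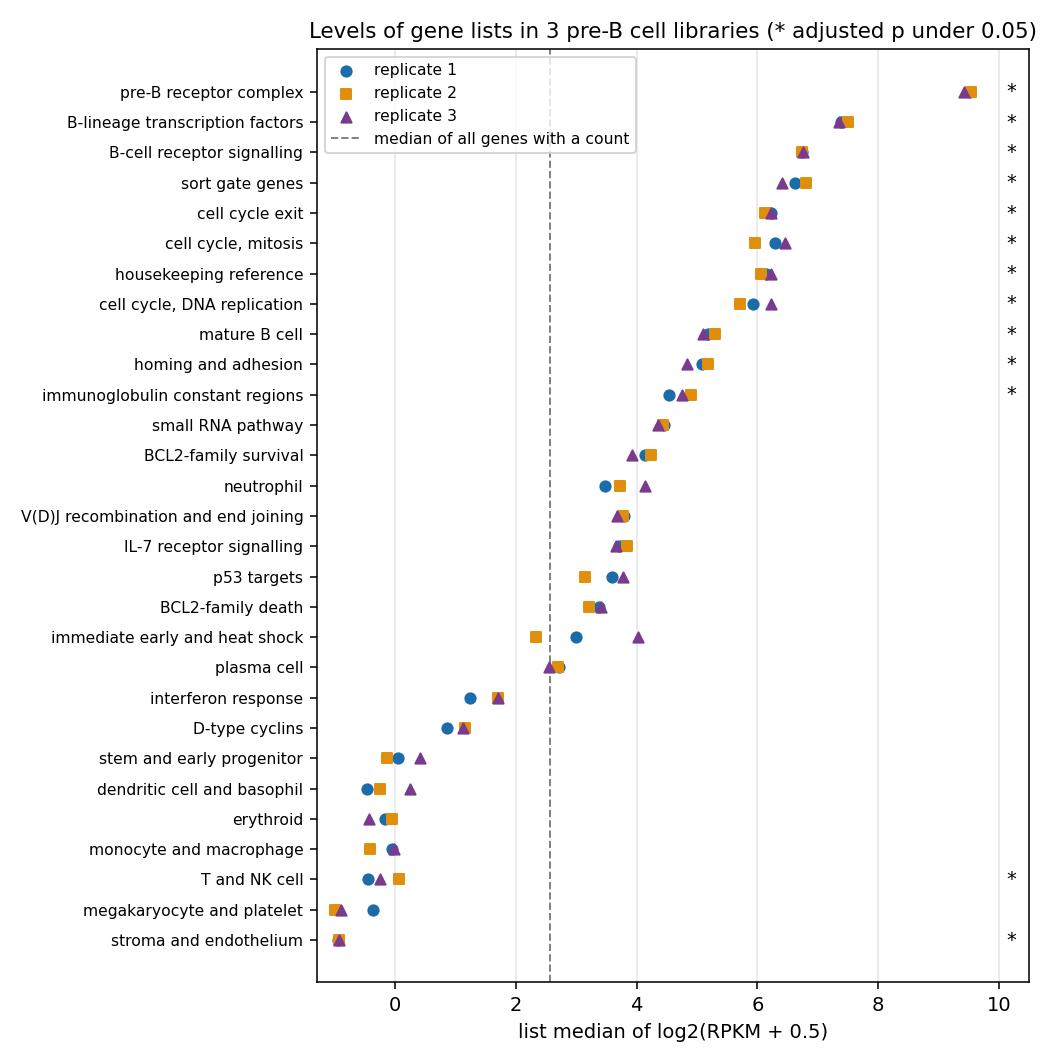
Median level of each of 29 gene lists, as log2(RPKM + 0.5), with 1 point per library and the median of all genes with a count as a dashed line. The pre-B receptor complex list lies highest, at 9.49, and the sex-linked list is left out because its members have opposite levels.

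In all, 11 of the 30 lists lay above and 2 below 10000 random lists of the same size (two-sided, Benjamini-Hochberg adjusted). The smallest adjusted p was 0.000857, from the smallest p that 10000 draws can give, and it was reached by the B-lineage factor, pre-B receptor, receptor signalling, both cell cycle, cell cycle exit and housekeeping lists. Sort gate genes (adjusted p = 0.0084), the mature B cell list (0.0040) and homing and adhesion genes (0.0202) were also high. Genes are not replicates, so these percentiles describe the 3 libraries. All 13 calls held without replicate 1, while 15 lists passed without replicate 3, which added the monocyte and macrophage and the dendritic cell and basophil lists.

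Markers of other cells were measured next, since a gate can hold them. Stem and early progenitor genes had a median of 0.10 ± 0.28, led by Lyl1 (43.0 ± 2.98 RPKM) and Erg (7.44 ± 3.19 RPKM), and Mecom had no counts, which allows up to 0.045 RPKM. B-lineage factors exceeded this list by 7.31 ± 0.34, 158.2-fold, a value that depends on the pseudocount (7.99 with 0.1 and 6.76 with 1) and was 8.14 with CPM. Mature B cell genes split: the invariant chain Cd74 (190 ± 7.02 RPKM), Cd38 (115 ± 26.1 RPKM) and the BAFF receptor gene Tnfrsf13c (108 ± 9.29 RPKM) were high, and the CD21 gene Cr2 (0.244 ± 0.106 RPKM) and the CD23 gene Fcer2a (0.185 ± 0.032 RPKM) low. The pre-B receptor list exceeded it by 4.30 ± 0.05, 19.7-fold (3.20 with CPM). In the plasma cell list, Mzb1 (197 ± 11.04 RPKM) and Slamf7 (92.7 ± 10.1 RPKM) contrasted with Tnfrsf17 (0.093 ± 0.014 RPKM), and the V(D)J list exceeded this list by 1.10 ± 0.02, 2.14-fold (3.05 on the log2 scale with CPM).

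T and NK cell genes were lower than random lists (adjusted p = 0.0471), with Lck highest at 8.87 ± 0.92 RPKM and Gata3 lowest at 0.027 ± 0.002 RPKM. Stroma and endothelium genes were lower too (adjusted p = 0.0022, and 0.0575 with low values filtered), led by Cdh5 at 1.37 ± 0.036 RPKM. Neutrophil genes were not low: S100a9 stood at 774 ± 250 RPKM, S100a8 at 546 ± 180 RPKM, Ngp at 173 ± 35.2 RPKM and Camp at 97.3 ± 25.7 RPKM, and all 15 members exceeded 1 RPKM in every library. Their median, 3.91, was not separated from random lists (adjusted p = 0.2502). The monocyte and macrophage list was not separated from random lists (adjusted p = 0.102), although with low values filtered it was lower (0.0060), as were the erythroid (0.0090) and the dendritic cell and basophil lists (0.0194), and 5 of its 15 members exceeded 1 RPKM in every library, led by Lyz2 (190 ± 36.0 RPKM), which neutrophils also express, and Itgam (15.4 ± 0.88 RPKM). Of the erythroid genes only Car2 (13.5 ± 1.66 RPKM) exceeded 10 RPKM, Hba-a1 stood at 4.38 ± 0.42 RPKM, and Itgb3 (7.99 ± 1.58 RPKM) led the megakaryocyte and platelet list. The basophil protease genes Prss34 (6.88 ± 6.63 RPKM) and Mcpt8 (3.32 ± 3.29 RPKM) led the dendritic cell and basophil list, with an SD close to the mean.

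The spread between the libraries was then measured gene by gene. Xist (Entrez 213742), the RNA that silences an X chromosome in female cells, had 22609 counts in replicate 1, 94 in replicate 2 and 70 in replicate 3, or 102, 0.44 and 0.12 RPKM. Mid1 (Entrez 17318), an X-linked ubiquitin ligase gene, had 8989, 159 and 371 counts, or 176, 3.24 and 2.81 RPKM. These were the only 2 of 12147 genes more variable than genes of like abundance in edgeR's intercept-only quasi-likelihood fit (adjusted p = 0.00018 for Xist and 0.000402 for Mid1). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 1, 0, 0 and 1 counts in replicate 1, against 1950, 1635, 1113 and 454 in replicate 2 and 4881, 3573, 2953 and 1140 in replicate 3. The filter on low counts needs its minimum in all 3 libraries, which kept these 4 genes out of the test. A gene absent from 1 library could therefore not be called. At an unadjusted p under 0.05 there were 644 genes. A robust fit called 0 (604 at an unadjusted p under 0.05), with Xist at an adjusted p of 0.996. That fit lowers the prior degrees of freedom of outlying genes, so its 0 does not weigh against Xist and Mid1. Testing all genes with a count called 46, and the count was 8 without replicate 1 and 44 without replicate 2.

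Counts of 6627 genes, 54.6% of those tested, differed between the libraries by more than Poisson noise (chi-square, Benjamini-Hochberg). No pair of libraries agreed within counting noise: 3141 genes differed between replicates 1 and 2, 4220 between 1 and 3 and 5506 between 2 and 3. The libraries were therefore not merged as reruns of 1 library, but this does not show separate animals. The biological coefficient of variation was 13.1%. The Poisson count was 4256 without replicate 2 and 3145 without replicate 3, and 5646 with replicate 3 thinned to the smallest total.

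Shifts of whole lists between libraries were next. Members of a list can move together, which random lists do not keep, so these p-values can be too small. They describe the 3 libraries only. The shifts of a gene over the 3 libraries sum to 0, so the 3 tests of a list are not independent. A shift given without a replicate is taken from the mean of the libraries kept, so its sign can turn through that change alone. Both cell cycle lists were highest in replicate 3, for all 16 members of each, and lowest in replicate 2, for all mitosis members and all but 1 of the DNA replication members. The median shift from the gene's mean over the libraries was 0.27 for DNA replication and 0.24 for mitosis in replicate 3, and -0.25 and -0.28 in replicate 2 (log2 CPM, adjusted p = 0.00147 for each). Set against replicate 2, replicate 3 had 1.43-fold more DNA replication transcripts and 1.42-fold more mitosis transcripts. Cell cycle exit genes did not pass in any library. The ribosomal RNA gene Rn28s1, named after its values were seen, had the same order, at 0.0257%, 0.0145% and 0.0467% of the counts of replicates 1, 2 and 3, so a difference in RNA or library preparation is not excluded. The immediate early and heat shock list went the same way, at 0.51 in replicate 3 and -0.41 in replicate 2, and all 12 tested members were highest in replicate 3, with Jun at 37.1, 23.3 and 68.5 RPKM and Jund at 134, 112 and 206 RPKM in replicates 1, 2 and 3. In replicate 1 this list shifted by -0.10 (adjusted p = 0.0432), and by 0.17 without replicate 3.

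Neutrophil transcripts were also highest in replicate 3, but lowest in replicate 1. Their shift was 0.41 in replicate 3 and -0.34 in replicate 1 (adjusted p = 0.00147 for both) and -0.13 in replicate 2 (0.0486), where it became 0.12 without replicate 3. S100a9 stood at 568, 702 and 1052 RPKM and S100a8 at 408, 481 and 749 RPKM in replicates 1, 2 and 3. Monocyte and macrophage genes were lower in replicate 1 (-0.23, adjusted p = 0.0295, and -0.06 with adjusted p = 0.475 without replicate 3). The 4 tested dendritic cell and basophil genes were all highest in replicate 3 (1.03, adjusted p = 0.00147). They were low in replicate 1 (-0.47) and in replicate 2 (-0.56, and 0.011 without replicate 3), with Prss34 at 36, 55 and 567 counts in replicates 1, 2 and 3.

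Shifts below 0 in replicate 3 passed for 3 lists. The mature B cell list shifted by -0.18 (adjusted p = 0.00147, and 0.0913 without replicate 1), the homing and adhesion list by -0.17 (0.00498, and 0.125 without replicate 1 or 0.106 without replicate 2), and the V(D)J list by -0.10 (0.0486, and 0.371 without replicate 1). Members went both ways in the mature B cell list (9 below and 7 above their mean), the homing and adhesion list (7 and 6) and the V(D)J list (10 and 6). Cxcr4 stood at 480, 394 and 344 RPKM and Rag1 at 424, 442 and 336 RPKM in replicates 1, 2 and 3. Interferon response genes were lower in replicate 1 (-0.28, adjusted p = 0.00147) and higher in replicate 2 (0.25, adjusted p = 0.0027, and 0.236 without replicate 1), and all 17 tested members were higher in replicate 2 than in replicate 1. Immunoglobulin constant regions shifted by -0.13 in replicate 1 (adjusted p = 0.00926), and by 0.0084 without replicate 2. Of 81 tests over 27 lists, 20 passed, against 12 without replicate 1 and 12 without replicate 3. With a replicate left out there are fewer tests and the shifts of a list mirror each other, so these counts cannot be compared directly.

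**Figure D2:**
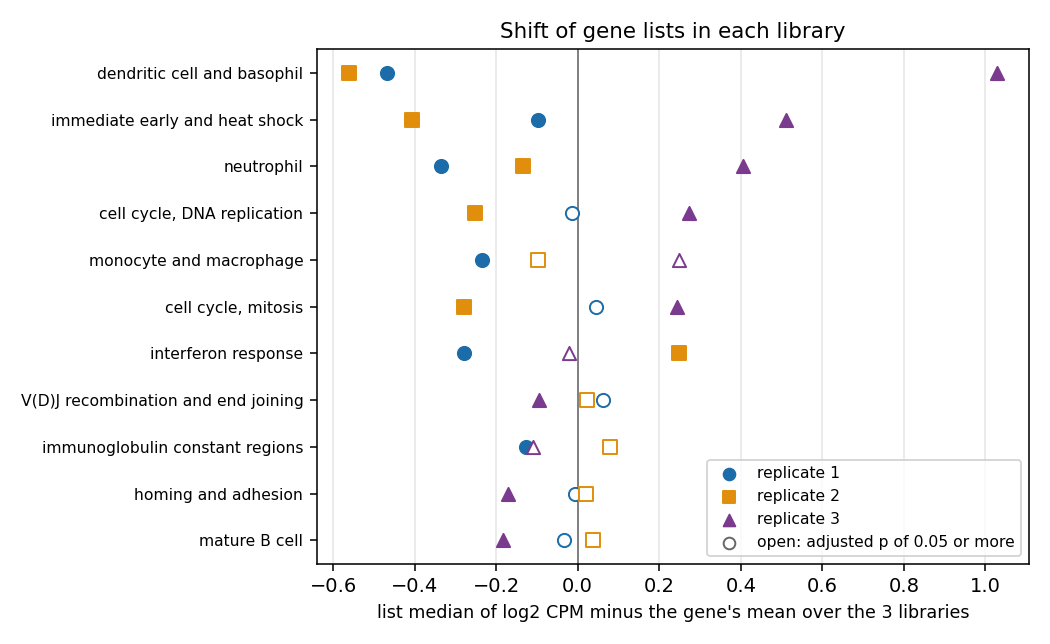
Median shift of the 11 lists with at least 1 call, as log2 CPM minus each gene's mean over the 3 libraries, with 1 point per library, filled where the adjusted p is under 0.05. Replicate 3 lies at 1.03 for dendritic cell and basophil genes, 0.51 for immediate early and heat shock genes and 0.41 for neutrophil genes, and replicate 2 lies lowest for both cell cycle lists.

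Apart from the replicate number and a sample code whose meaning is not given, the labels differed in the version of CASAVA, Illumina's base-calling software: 1.8.0 for replicate 3 and 1.8.2 for the others. Of 12147 genes, 7 were higher and 2 lower in replicate 3 in edgeR's quasi-likelihood test. The higher genes included the annotated pseudogenes Gm15710, with a log2 fold change of 1.85 ± 0.16 (SE, adjusted p = 0.0448 as for each of the 9), Gm10240 (2.07 ± 0.21) and Gm5643 (2.27 ± 0.25). With them were Gm12657 (2.09 ± 0.22) and Cyp4f18, a cytochrome P450 gene (1.61 ± 0.17). Dhrs3, a retinal reductase gene (-1.999 ± 0.22), and Entrez 100044751 (-1.13 ± 0.13) were lower. The neutrophil, dendritic cell and basophil, and cell cycle lists also had median shifts above 0 in this library, as given above. Of the 279 list members tested, 0 passed over all genes tested, with 1169 of all genes at an unadjusted p under 0.05. Adjusted over the list alone, 43 genes of 11 lists passed, 38 of them higher in replicate 3. Among the higher were 11 immediate early and heat shock genes, 10 DNA replication genes, 9 neutrophil genes and 3 dendritic cell and basophil genes. The 5 lower were Kit, Bmf, Xist and the p53 targets Sesn1 and Zmat3, the last pair named after its values were seen. Xist was the only gene tested of its list, so it had no adjustment, and its difference comes from replicate 1. With 1 library on one side, the version cannot be told apart from that sample. DESeq2 called 36 genes, which held all 9, while testing all genes with a count or thinning replicate 3 to the smallest total called 0 (lowest adjusted p 0.397 and 0.0584, with 1200 and 1103 genes at an unadjusted p under 0.05). The folds stayed near their values there, with Gm15710 at 1.85 and 1.86 and Dhrs3 at -1.999 and -2.15, so the calls ended through the adjusted p.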

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

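The thinning of replicate 3 and the list shifts without a replicate were chosen after seeing the data. The counts of detected genes, of list calls and of differences with 1 sign, and the biological coefficient of variation, stayed within 1.5 times their value under all alternatives tried. Genes varying beyond Poisson noise numbered 3145 to 5590 with 1 replicate left out, where fewer libraries are compared. Genes more variable than those of like abundance numbered 46 when all genes with a count were tested, 0 in a robust fit and 2 to 44 with 1 replicate left out. The robust fit discounts outlying genes, so its 0 does not weigh against the calls of Xist and Mid1. For the CASAVA version, DESeq2 called 36 genes, and testing all genes with a count or thinning replicate 3 called 0 each. List shifts past the threshold numbered 12 to 18 with 1 replicate left out, where fewer tests are run and the shifts of a list mirror each other. The cause of the other changes was not tested.

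Cell cycle exit minus mitosis ranged from -0.15 to 0.044 with 1 replicate left out, and cell cycle exit minus DNA replication was -0.51 with CPM, which drops gene length. Shifts that turned with 1 replicate left out were those of neutrophil genes in replicate 2 (-0.28 to 0.12), dendritic cell and basophil genes in replicate 2 (-0.75 to 0.011), immediate early and heat shock genes in replicate 1 (-0.33 to 0.17) and immunoglobulin constant regions in replicate 1 (-0.16 to 0.0084). Leaving out a replicate changes the mean that a shift is taken from, so these turns do not by themselves show a dependence on processing. No paired analysis was possible because there is 1 group, and the CASAVA comparison without a replicate leaves no residual degrees of freedom, so it was not run. The level of Kit, 0.791 RPKM, is near the pseudocount and moved with it. Differences of lists and of genes also moved with CPM, as in V(D)J minus plasma cell genes (1.10 to 3.05).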

Other observations

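The one-against-the-rest tests beyond that of CASAVA were planned. Chosen only after the results were seen were the segment shares, the chaperone list, the ratio of light chains, the pseudogene tests on the ranking of 200 genes, the comparison with other lineages, and the tests of Y-linked genes, of Mid1 and of the groupings. Of these pseudogene tests, the sequence test had its prediction written before its own result was seen, though the idea came from that ranking. Counts of the heavy chain and kappa loci were spread over many variable segments, in similar proportions within a locus in the 3 libraries, while of the 3 lambda segments Iglv1 took 65.6 ± 2.72%. They do not tell rearranged from unrearranged transcripts, and kappa segments took 0.0620%, 0.0565% and 0.0464% of all counts in replicates 1, 2 and 3. Of 116 annotated heavy chain segments, 98, 97 and 105 had at least 10 counts in replicates 1, 2 and 3, and the highest, Ighv8-8, took 4.40 ± 0.18% of the heavy chain segment counts (SD, n = 3). The inverse Simpson number was 55.4 ± 0.62 segments for the heavy chain and 39.2 ± 0.93 for kappa, where Igkv1-135 took 10.9 ± 0.59%. Across segments, which are not independent replicates, Spearman's rho between libraries was 0.987 to 0.992 for the heavy chain and 0.956 to 0.973 for kappa. Igkc counts exceeded the summed lambda constant region counts by 3.11, 2.04 and 2.28-fold in replicates 1, 2 and 3, and the near-identical segments make single values uncertain.

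Chaperone genes were lowest in replicate 2. All 14 tested members of a chaperone list were below both other libraries there, by a median of -0.44 on the log2 scale, with Hspa8 at 244, 144 and 287 CPM and Hsph1 at 83.1, 43.1 and 84.5 CPM in replicates 1, 2 and 3. Cirbp, a cold-inducible RNA-binding protein gene, went the other way at 55.1, 110.4 and 47.6 CPM, while Rbm3, another cold-inducible gene, stood at 44.7, 45.98 and 36.7 CPM. In edgeR's fit of replicate 2 against the other libraries, the log2 fold changes were -0.88 for Hspa8, -0.96 for Hsph1 and 1.11 for Cirbp. With 1 library on one side, these values describe that library only. Fos, also chosen after its values were seen, stood at 4.83, 1.502 and 22.3 CPM in replicates 1, 2 and 3.

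Among the 200 genes highest in replicate 3 over the other libraries, 24 were annotated pseudogenes, against 5.94 expected from their share and 7 and 3 in the same ranking of replicates 1 and 2. The 200 lowest genes held 16, 20 and 3 pseudogenes in the rankings of replicates 1, 2 and 3. The class as a whole moved little: of 361 tested pseudogenes 208 were higher in replicate 3, with a median log2 difference of 0.058. The same median was -0.0053 for replicate 1 and -0.055 for replicate 2, so replicate 2 was about as far below the others as replicate 3 was above. All annotated pseudogenes took 3.73%, 3.73% and 3.62% of the counts of replicates 1, 2 and 3. The pattern was first framed as all 28 tested ribosomal protein pseudogenes, and there the ribosomal protein genes shifted by about as much (difference of medians -0.057, SE 0.12) and the median shift of 0.15 (0.13 after thinning, SE 0.11) left depth open; the ranking of 200 genes replaced it only after that result was seen. In the ranking, depth is argued against, since after thinning the top 200 held 26 pseudogenes, among them all 24 found at full depth, but a change in the parent genes stays open: the parents of 6 ribosomal protein pseudogenes (5 annotated as such) shifted less, by -1.38 (SE 0.24), which picking these 6 for a high value favours, and for the 19 others no parent was set beside them. Reads shared between near-identical genes and counted differently in this library are a possible explanation. The sequence test gave an odds ratio of 2.57 for protein-coding genes with at least 50% of their 31-base words in another gene. That was a one-sided Fisher's exact p of 0.00123, and the ratio was 1.07 and 0.61 in replicates 1 and 2. This goes with the explanation, but the test does not measure how reads were counted. It cannot tell such counting from a change in the expression of these genes, and the idea came from genes seen in that ranking. The CASAVA 1.8.0 run holds 1 library and cannot be told apart from it, and no biological explanation was tested.

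Neutrophil transcripts differed most between replicates 3 and 1, with a median 1.68-fold over the 15 listed genes, and S100a8 and S100a9 stood above 400 RPKM even in replicate 1. A lower share of pre-B cells that raised every other lineage alike is not excluded. T and NK, erythroid, and monocyte and macrophage genes together differed by less (-0.49 relative to the neutrophil list on the log2 scale, SE 0.22, over 17 genes). That SE comes from resampling genes, not samples, and RNA of these genes from the pre-B cells themselves could also lower their ratio. The lists moved apart, at 0.97-fold for erythroid, 1.23-fold for T and NK, 1.45-fold for monocyte and macrophage and 2.62-fold for dendritic cell and basophil genes. Of these lists taken alone, only the erythroid one, with 3 genes, was separated from the neutrophil list by over 2 SE (-0.79, SE 0.13). Neutrophil RNA or cells carried into the samples may account for it: in a second neutrophil list, with no member in the first, 16 of 16 genes were higher in replicate 3 than in replicate 1 (median 1.57-fold), as for Retnlg at 28.7 and 51.0 CPM. The gate on B220 and CD25 should remove neutrophils, the pre-B cells' own expression of these genes is not measured here, and no biological explanation was tested.

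Xist and Mid1 were high in replicate 1 alone, as was Scn4b (27.2, 4.59 and 3.14 CPM, named after its values were seen). In edgeR's fit of replicate 1 against the others, the log2 fold change of Scn4b was 2.85, with 1 library on one side. A Y chromosome in replicate 1 is argued against, since 4 of 4 Y-linked genes had at most 1 count there and 454 or more in the other libraries. A female donor for replicate 1 and male donors for the others is a candidate explanation that the Xist and Y-linked counts go with. Under it, any other difference of replicate 1 from the other libraries cannot be told apart from donor sex. The X-linked partners alone left sex open: 3 of 4 were higher in replicate 1 than in both others (Kdm6a 1.45-fold, Kdm5c 1.43-fold, Eif2s3x 1.34-fold), and Ddx3x was not, at 0.90-fold. The Xist and Y-linked counts argue against the same donors for replicate 1 and the other libraries. An added X chromosome alone is argued against as the cause of the Mid1 difference, which was 58.8-fold. The labels used here give no sex.

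For the CASAVA comparison, the 3 ways to set 1 library against 2 are too few for a share under 0.05. The real grouping gave 9 genes and the highest other 14, for replicate 2, so that 2 of the 3 gave at least as many.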
